A study of Rattus norvegicus with 4 samples.

How the data were processed

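RNA bound to Argonaute 2 (Ago2), the protein that carries microRNAs in the silencing complex, was immunoprecipitated from rat kidney lysate (RNA immunoprecipitation, RIP) and sequenced beside input RNA of the same lysates. The labels name 4 libraries, an IP and an input library of a kidney labelled 148 and an IP and an input library of a kidney labelled CK, so each group holds 1 library. The labels do not expand 148 or CK, and both names are used here as given. An IgG control named in the protocol was not analysed here. Per the labels' protocols, RNA was converted to cDNA and libraries were made with an NEBNext Ultra RNA kit for Illumina sequencing.

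Reads were demultiplexed with bcl2fastq and aligned with TopHat2 2.0.13 to the rn6 assembly, per the submitters' processing notes. The read counter, the annotation release and the strand setting are not given in the sources used here. The authors deposited, for each library, a whole-number read count and an RPKM value for each RefSeq transcript model. The deposited RPKM values are scaled to transcript length and to the library total, and they were used here only to recover transcript lengths. For each IP library the authors deposited a peak list whose columns hold a read count, a signal in reads per kilobase, a log odds score, a p-value, an adjusted p-value and an empirical FDR, per the file headers. The peak caller is not given in the sources used here, and all peak scores and p-values quoted are the authors'. A control column accompanies each peak without a name in the header. At Rn5s its ratio to the IP reads was 0.115 in the 148 list and 0.222 in the CK list, beside input over IP count ratios of 0.116 and 0.186. The authors' deposited table of differential peaks gives positions on rn6, a whole-number signal of at least 1 for each IP library and a Z score, per the file headers. Its normalization and test are not given in the sources used here. The signals are not counts, because both columns share their highest values. The number of per-sample columns left unused was 0.

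Counts of 60711 transcript models were summed by gene ID to 29474 genes. Gene symbols are those of the deposited files. Of these genes, 23371 matched by gene ID to a GRCr8 annotation table, which was used only for names and neighbours. Genes with several transcript models numbered 11729 (39.8%) and held 14.6% to 20.0% of the counts outside 7SL RNA, so counts of such genes are uncertain. Of the 123 CK peaks in exons or UTRs of genes with several models, 67 lay in genes that the CK IP count table lists at 0, against 3 of 71 for genes with a single model. In the 148 list these numbers were 18 of 33 and 2 of 19. A gene at 0 with several models is therefore not taken as undetected.

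Ratios between libraries were computed as log2 of CPM, the counts scaled to the library total, with a pseudocount of 1, over genes with at least 50 counts in 1 or more of the compared libraries. Genes were called higher or lower at 2-fold. With 1 library per group there is no replicate check on any difference, and no p-value, SD or test across genes is given. Because 1 transcript, 7SL RNA, took most counts, folds of single genes and gene lists are given per count outside 7SL RNA, with the exact conditional binomial 95% interval of the ratio of the counts. Shares carry exact Clopper-Pearson intervals and list levels exact Poisson intervals. These reads carry no molecular identifiers and are not independent molecules, so the intervals and floors cover counting error only. Against a library with 0 counts a fold is a lower bound, computed with a floor of 3 counts per library. That floor corresponds to 16.4 CPM in the 148 IP, 7.51 in the 148 input, 5.87 in the CK IP and 8.03 in the CK input library.

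The comparisons were IP over input in each kidney, 148 IP over CK IP, 148 input over CK input, and the difference of the log2 enrichments of the kidneys. Groups, tests, alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The rule named Ago2 and Calcr always, and the 10 highest and 10 lowest genes with a proper symbol and at least 200 counts in the higher library. It also named up to 4 members of each list past the count minimum, and the genes of the 10 largest differential peaks in each direction and of the 5 highest-scoring peaks of each list. Some genes that the rule named are not reported here. Further genes are said to have been chosen after their values were seen. Gene lists were summarised by summed counts, by the calls of their members past the minimum and by the percentile of their median ratio among 10000 random lists matched on expression in 20 bins. So few genes passed the minimum that matching left little choice of other genes. Peak sets were compared by overlaps of at least 1 bp, and the chance overlap was taken from 1000 random shifts of the peaks along their chromosomes.

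Alternatives were TMM scaling with edgeR 4.0.16 in R 4.3.3, pseudocounts of 0.1 and 5, no count minimum, the minimum in every compared library, protein-coding genes only, unmatched random lists, 50% reciprocal overlap and stricter peak sets. Scaling to counts outside 7SL RNA, alone or with another count minimum, restriction to genes with a single transcript model and splitting the differential table by Z score were added after seeing the data, as were lists of muscle and neuron genes and of abundant housekeeping genes. A search for microRNA seed matches was not run, because no transcript sequences were used here. Analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.

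The calls were tested on simulated counts for 148 IP over CK IP with 200 changed genes among the 29474. At the depth of these libraries, 1 gene changed 4-fold and 6 genes changed 8-fold passed the count minimum, and all of them were called. None of the 28 and 24 unchanged genes past the minimum was called. Both simulated libraries came from the same pooled profile and so had nearly the same 7SL share. The simulation thus leaves out the shift of 1.03 that the 7SL share puts on log2 CPM ratios in this comparison. At 20 times the depth, 197 and 200 of the 200 changed genes were called, beside 10 of 4058 and 15 of 4073 unchanged genes. The intervals covered the true fold of 96% to 100% of the changed genes that had reads. The simulated counts varied by counting error alone, for which exact intervals are built. This coverage therefore does not show how the intervals perform on real libraries.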

Results

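Ago2-bound RNA and input RNA from 2 rat kidneys, labelled 148 and CK, were compared in 4 sequencing libraries. The series concerns miR-148b-5p, the circular RNA circRNA-83536, miR-24-3p and the calcitonin receptor gene Calcr in hypercalciuric kidney stones, and Ago2 RIP was meant to screen for RNAs under control of the microRNA. Reads counted on transcripts numbered 182691 in the 148 IP, 399541 in the 148 input, 511087 in the CK IP and 373719 in the CK input library.

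7SL RNA (LOC102723236, chr6:91456912-91457210, rn6), the RNA of the signal recognition particle, took most of every library. Its share was 83.6% in the 148 IP (95% interval 83.4% to 83.7%), 92.8% in the 148 input, 92.0% in the CK IP and 93.2% in the CK input library. Outside 7SL RNA there remained 30034 counts in the 148 IP, 28652 in the 148 input, 41085 in the CK IP and 25346 in the CK input library. Only 55 genes reached 50 counts in any library, 48 of them in the CK IP library and 17 in the 148 IP library. The protein-coding share of counts outside 7SL RNA was 81.3% (80.9% to 81.6%) in the CK IP library, against 69.5% in the 148 IP, 72.2% in the 148 input and 71.9% in the CK input library. Ribosomal RNA made up 3.38% and 3.09% of those counts in the 148 and CK IP libraries, and 0.907% and 0.659% in their inputs. MicroRNA genes had 24, 44, 32 and 38 counts in the 148 IP, 148 input, CK IP and CK input libraries. They made up less of the IP libraries, 0.0799% (0.0512% to 0.119%) and 0.0779% (0.0533% to 0.110%), than of their inputs. The inputs held 0.154% (0.112% to 0.206%) and 0.150% (0.106% to 0.206%). Whether these reads came from mature microRNAs was not examined, so the shares do not show how much microRNA was bound to Ago2. Dividing by all counts in place of those outside 7SL RNA shifted log2 ratios, apart from what the pseudocount does at low counts, by 1.20 for IP over input in the 148 kidney, 0.25 in the CK kidney, 1.03 for 148 IP over CK IP, 0.08 for the inputs and 0.95 for the difference of enrichments. Gene and list folds in the following are per count outside 7SL RNA and so stand clear of this shift.

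The first comparison asked which RNAs were enriched with Ago2 over the lysate of the CK kidney. Messenger RNAs of the proximal tubule, the segment that reclaims most of the filtrate, were higher in the CK IP than in its input. Proximal tubule markers summed to 658 counts in the IP and 53 in the input, a 7.66-fold difference (5.78 to 10.3). Among the genes past the count minimum its median ratio was at percentile 41.65 of matched random lists and 89.21 of unmatched ones. The matched value cannot tell whether the list stood out, because the random median equalled the list's own, at a log2 ratio of 3.39. With no minimum the list stood at percentile 99.69 of matched lists. Lrp2, the endocytic receptor megalin (chr3:55665153-55822484), was 9.06-fold higher (5.46 to 16.1), and Pck1, a gluconeogenic enzyme (chr3:171213936-171219885), 8.88-fold (4.69 to 18.9). Slc34a1, the main phosphate transporter of this segment (chr17:9747766-9762739), had 57 counts in the IP and 1 in the input (35.2-fold, 6.06 to 1413), and Slc3a1, a subunit of the cystine transporter, had 56 and 1 (34.5-fold, 5.95 to 1389). Cubn, the receptor cubilin, was 3.21-fold higher (1.61 to 7.08).

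Other abundant messenger RNAs were higher in the CK IP library too. Eef1a1, a translation elongation factor, was 27.1-fold higher (13 to 67.9), and Syne2, a giant protein of the nuclear envelope, 9.53-fold (6.45 to 14.6). Ribosomal protein genes were 4.99-fold higher as a group (3.88 to 6.5), with Rplp0 at 68 and 1 counts (41.9-fold, 7.28 to 1681). Fatty acid oxidation genes were 6.21-fold higher (3.71 to 11.1), led by Cyp4a2 at 8.53-fold (3.76 to 23.9). Nuclear genes of oxidative phosphorylation were 2.77-fold higher (1.84 to 4.29). The calcium and phosphate handling list was 3.48-fold higher (2.07 to 6.23), but 1.5-fold (0.821 to 2.88) without Slc34a1. Chosen after its values were seen, the sodium pump subunit Atp1b1 had 67 counts in the IP and 0 in the input (at least 13.8-fold). The ribosomal RNAs were also higher, Rn45s, the ribosomal RNA precursor, by 5.29-fold (4.36 to 6.47) and Rn5s, the 5S ribosomal RNA, by 3.31-fold (2.45 to 4.56).

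Genes lower in the CK IP than in its input were few. Atp6v1b1, a proton pump subunit of collecting duct intercalated cells (chr4:115417100-115435754), had 3 counts in the IP and 283 in the input, 153-fold lower (51.8 to 746). It carried the collecting duct list, which was 10.4-fold lower with it (7.60 to 14.5) and 2.21-fold higher without it (1.14 to 4.61). Of the 43 IP and 12 input counts without Atp6v1b1, Aqp2, chosen after its values were seen, held 26 and 0. Hmox2-ps1, a pseudogene, was 1.60-fold lower (1.43 to 1.79). Olfactory and vomeronasal receptor genes, the odour and pheromone receptors of sensory neurons, were 1.77-fold lower (1.49 to 2.10). The gene listed as Rmrp (chr15:27738989-27739245), whose gene ID the GRCr8 table names Rpph1, the RNA of ribonuclease P, was 1.15-fold lower per count outside 7SL RNA (1.06 to 1.25), a direction that flips on CPM with a log2 ratio of 0.04. MicroRNA machinery genes differed by 1.03-fold (0.582 to 1.86), within counting error, and Ago2 itself had 10 counts in the IP and 2 in the input (3.09-fold, 0.657 to 29.0). On CPM, 38 of 51 genes were at least 2-fold higher and 5 lower, with a median log2 ratio of 2.62, but only 11 of them reached the minimum in both libraries, and of these 2 were higher and 3 lower (median -0.02). With no minimum 5480 genes were higher and 5097 lower (median -0.03), or 5403 and 5228 per count outside 7SL RNA, so the excess among the 51 goes with the minimum, which most genes reached through the IP library alone.

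**Figure D1:**
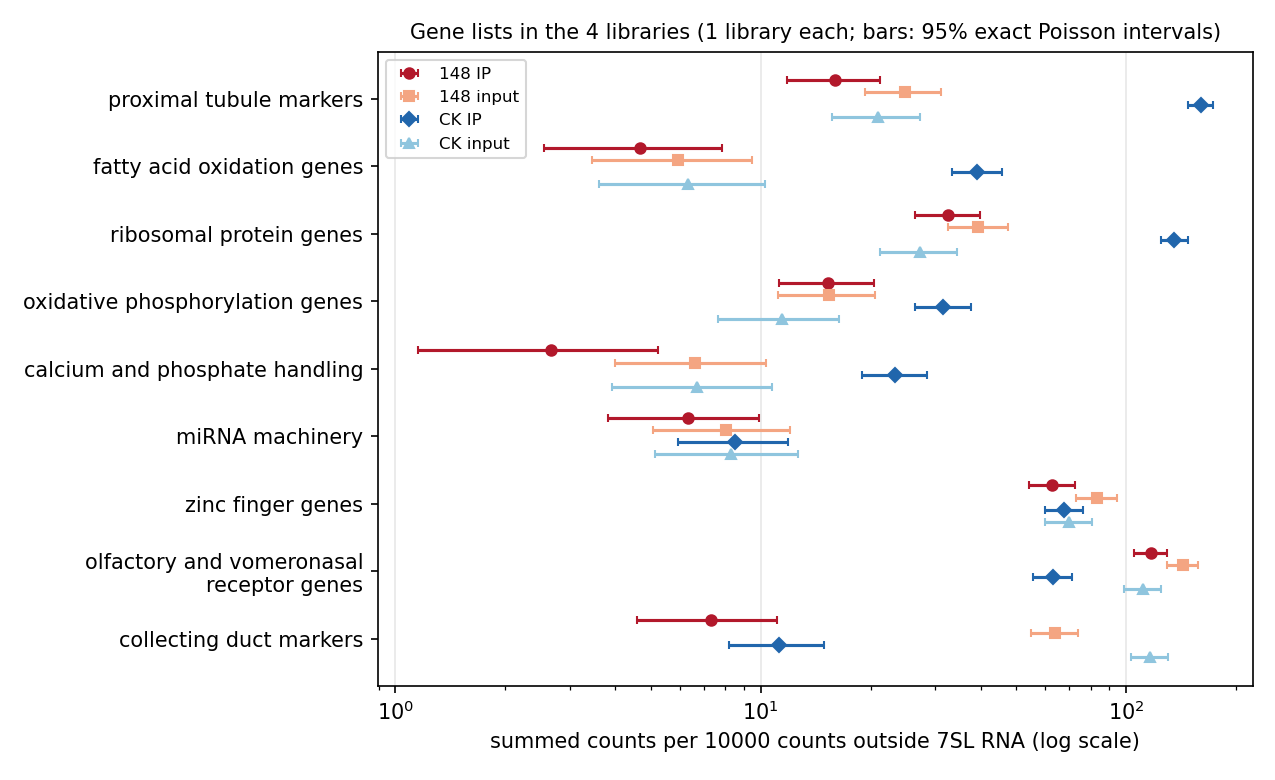
Summed counts of 9 gene lists per 10000 counts outside 7SL RNA (log scale) in the 4 libraries, with 1 point per library and 95% exact Poisson intervals as bars. Proximal tubule markers stood at 160 in the CK IP library and at 16.0, 24.8 and 20.9 in the 148 IP, 148 input and CK input libraries, and collecting duct markers were higher in both inputs through Atp6v1b1 alone.

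The same question in the 148 kidney gave a partly different set of genes. Rn5s (chr12:1510398-1510517) was the most enriched named gene, with 793 counts in the IP and 92 in the input (8.22-fold, 6.62 to 10.3). LOC103692483, a long non-coding RNA chosen after its values were seen (chr5:150525975-150530342), had 135 counts in the IP and 0 in the input, at least 42.9-fold higher. Like Rn5s, LOC103692483 was higher in the CK IP than in its input too, at 28 and 1 counts (17.3-fold, 2.86 to 706). Proximal tubule markers were not enriched, with 48 counts in the IP and 71 in the input (1.55-fold lower, 1.06 to 2.29). Without Pck1 the ratio was 0.839 (0.547 to 1.28), within counting error. Calcium and phosphate handling genes were 2.49-fold lower (1.04 to 6.57) on 8 and 19 counts, and had a ratio of 0.382 (0.121 to 1.04) without Slc34a1. Eef1a1 had 1 count in the IP and 32 in the input (33.5-fold lower, 5.60 to 1366). Atp6v1b1 was 59.7-fold lower (20.1 to 293), and without it the collecting duct list differed by 1.51-fold (0.696 to 3.41).

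Ribosomal protein genes in the 148 kidney differed by 1.21-fold (0.914 to 1.60, lower in the IP), oxidative phosphorylation genes by 1.0-fold (0.648 to 1.55), fatty acid oxidation genes by 1.27-fold (0.591 to 2.79) and microRNA machinery genes by 1.27-fold (0.661 to 2.46), none beyond counting error. Without Acadm, at 8 and 1 counts, fatty acid oxidation genes were 2.80-fold lower (1.04 to 8.72). Rn45s was 1.27-fold higher (1.03 to 1.56) and Hmox2-ps1 1.24-fold higher (1.12 to 1.37). Rmrp was 1.07-fold lower (0.987 to 1.17) per count outside 7SL RNA, while CPM put it higher with a log2 ratio of 1.09. Ago2 had 4 counts in the IP and 5 in the input. Of 19 genes, 13 were at least 2-fold higher and 1 lower on CPM, but 3 and 3 with TMM scaling and 4 and 3 per count outside 7SL RNA. The lower 7SL share of the 148 IP library raises the CPM of all other genes in it together.

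Ago2-bound RNA was next compared between the kidneys, the contrast of the authors' own differential table. Messenger RNAs of the proximal tubule and of several abundant genes were far lower in the 148 IP than in the CK IP library. Proximal tubule markers were 10-fold lower (7.47 to 13.7). Lrp2 was 15.6-fold lower (8.57 to 31.7), Pck1 26.3-fold (10.1 to 97.9), and Slc34a1, with 2 counts, 20.8-fold (5.51 to 176). Cubn was 3.17-fold lower (1.67 to 6.52), short of 2-fold on CPM. Syne2 was 14.5-fold lower (9.37 to 23.7), and Eef1a1, with 1 count against 307, 224-fold (40.0 to 8893).

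Ribosomal protein genes were 4.16-fold lower in the 148 IP library (3.35 to 5.21), fatty acid oxidation genes 8.41-fold (4.87 to 15.7), oxidative phosphorylation genes 2.07-fold (1.47 to 2.96) and calcium and phosphate handling genes 8.77-fold (4.28 to 20.9). Without Cyp4a2 fatty acid oxidation genes were 4.07-fold lower (2.29 to 7.79), and without Slc34a1 calcium and phosphate handling genes 4.75-fold (2.00 to 13.7). Oxidative phosphorylation genes were 1.48-fold lower (1.02 to 2.17) without Atp5b. Rplp0 was 7.10-fold lower (3.27 to 18.3), and Cyp4a2, with 0 counts against 83, at least 20.2-fold. Fth1, the ferritin heavy chain, had 0 counts against 134, at least 32.7-fold lower. Red blood cell markers had 0 counts against 24, 18 of them of Hbb (beta globin). Rn45s was 3.26-fold lower (2.82 to 3.79). Stone and crystal proteins were 5.24-fold lower (2.22 to 15.1; 3.84-fold, 1.29 to 15.4, without Xdh), and endothelial markers 2.92-fold (1.38 to 6.90; ratio 0.737, 0.249 to 1.99, without Kdr). Collecting duct markers differed by 1.53-fold (0.901 to 2.67), podocyte markers by 1.63-fold (0.822 to 3.42) and distal convoluted and connecting tubule markers by 1.46-fold (0.552 to 4.28), all lower in the 148 IP but within counting error, and the first with a ratio of 1.5 (0.784 to 2.91) without Aqp2. Thick ascending limb markers, on 2 and 22 counts, were 8.04-fold lower (1.98 to 70.5), with a ratio of 0.195 (0.0216 to 0.851) without Kcnj1.

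Other RNAs were higher in the 148 IP library. Rn5s was 3.96-fold higher (3.45 to 4.56), Hmox2-ps1 2.05-fold (1.85 to 2.27), and LOC103692483, chosen after its values were seen, 6.60-fold (4.37 to 10.3). Olfactory and vomeronasal receptor genes were 1.85-fold higher (1.57 to 2.18) and muscle and neuron genes, a list added after seeing the data, 3.31-fold (2.32 to 4.80). Both lists were also higher in the 148 input than in the CK input, by 1.29-fold (1.11 to 1.51) and 1.54-fold (1.13 to 2.10), and muscle and neuron genes were 2.49-fold lower in the CK IP than in its input (1.68 to 3.70). Rmrp differed by 1.02-fold (0.937 to 1.10), microRNA machinery genes by 1.35-fold (0.749 to 2.49, lower in the 148 IP) and published miR-24-3p targets by 1.42-fold (0.798 to 2.53), all within counting error. On CPM 15 of 54 genes were at least 2-fold higher and 35 lower, a split that became 9 and 38 with TMM scaling and 10 and 38 per count outside 7SL RNA. Only 11 genes reached the minimum in both libraries, and of these 9 were higher and 0 lower on CPM but 5 and 2 per count outside 7SL RNA. With no minimum, 6378 were higher and 4918 lower on CPM, which carries the shift of 1.03, but 5300 and 5555 per count outside 7SL RNA.

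**Figure D2:**
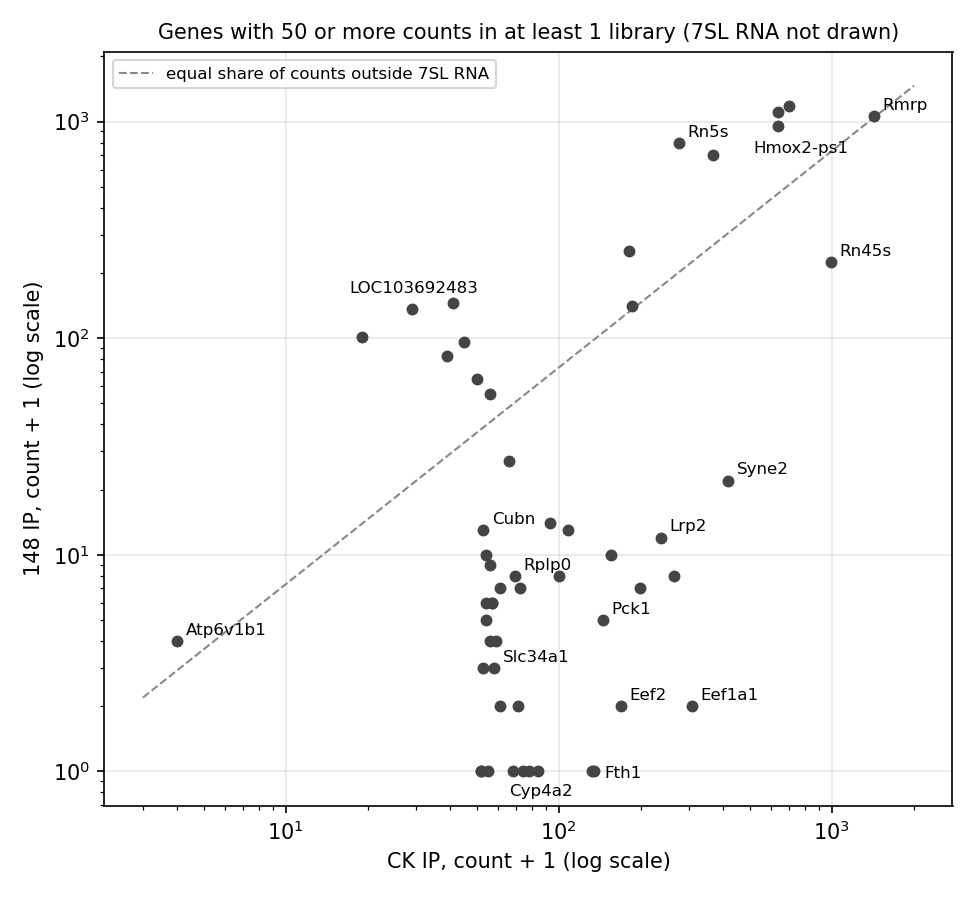
Counts plus 1 of each gene that reached 50 counts in at least 1 library, in the CK IP library (horizontal, log scale) and the 148 IP library (vertical, log scale), with 1 point per gene and 7SL RNA not drawn. The dashed line marks an equal share of the counts outside 7SL RNA, with Eef1a1 (307 and 1 counts) below it and Rn5s (274 and 793) above it.

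The inputs addressed whether RNA levels themselves differed between the kidneys. Several kidney lists did not differ beyond counting error, on intervals too wide at this depth to call levels equal. Among them, thick ascending limb markers were 3.11-fold lower in the 148 input (0.921 to 13.4) and podocyte markers 1.63-fold lower (0.646 to 4.33). Fibroblast and smooth muscle markers were 3.24-fold higher (0.857 to 18.1). Collecting duct markers were 1.82-fold lower (1.51 to 2.20), with a ratio of 0.885 (0.364 to 2.15) without Atp6v1b1. Proximal tubule markers differed by 1.19-fold (0.819 to 1.73), fatty acid oxidation genes by 1.06-fold (0.503 to 2.24, lower in the 148 input) and oxidative phosphorylation genes by 1.34-fold (0.821 to 2.22). Ribosomal protein genes were 1.45-fold higher in the 148 input (1.06 to 1.98) and 1.33-fold (0.962 to 1.84) without Rpl7a, and Eef1a1, at 32 and 7 counts, 4.04-fold higher (1.75 to 10.9). Atp6v1b1 was 1.87-fold lower in the 148 input (1.54 to 2.28) and Syne2, on 11 and 27 counts, 2.77-fold lower (1.33 to 6.20). Distal convoluted and connecting tubule markers were 3.01-fold lower in the 148 input (1.12 to 9.41) on 6 and 16 counts, of which Trpm6 held 6 and 4. Urothelium markers had 8 counts against 0, 6 of them of Krt5. Stone and crystal proteins were 7.91-fold lower (2.36 to 41.4) on 3 and 21 counts, of which Xdh, xanthine dehydrogenase, held 0 and 8, and 4.90-fold lower (1.35 to 26.8) without it. Inflammation genes were 2.56-fold higher in the 148 input (1.16 to 6.20), with the NF-kappa-B inhibitor Nfkbia at 14 and 2 counts, and 1.52-fold (0.550 to 4.55) without it. Of 15 genes past the minimum, 0 were 2-fold higher and 0 lower, with a median log2 ratio of 0.00.

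Setting the enrichment of the 148 kidney against that of the CK kidney corrects the Ago2 comparison for the input levels. Proximal tubule markers were 11.9-fold less enriched in the 148 kidney (7.49 to 18.8) and ribosomal protein genes 6.03-fold (4.17 to 8.72). Fatty acid oxidation genes were 7.90-fold less enriched (3.30 to 18.9), and 4.32-fold (1.57 to 11.9) without Cyp4a2. Oxidative phosphorylation genes were 2.77-fold less enriched (1.56 to 4.94), and 2.06-fold (1.13 to 3.73) without Atp5b. The proximal tubule median was at percentile 87.13 of matched random lists, 39.54 of unmatched ones and 25.96 with no minimum. The first 2 values rested on 5 members past the minimum, and most members added without it had few reads. These percentiles disagree and cannot tell whether the list stood out from other genes. On CPM, the difference in log2 enrichment was -4.57 for Pck1, -4.82 for Slc34a1, -2.41 for Lrp2 and -4.10 for Rplp0. Per count outside 7SL RNA, with the pseudocount, it was -5.60, -6.16, -3.37 and -5.42 in the same order. These single-gene differences carry no interval, and counting error leaves their size uncertain. Slc34a1 had 2, 4, 57 and 1 counts in the 148 IP, 148 input, CK IP and CK input libraries, and Rplp0 7, 7, 68 and 1. Rmrp stood at 1.05 on CPM and 0.10 per count outside 7SL RNA. Atp6v1b1 was depleted in both IP libraries. Across the 55 genes, which are not independent replicates, the enrichments of the kidneys had a Pearson r of -0.05 and a Spearman rho of -0.19. On CPM 17 genes were at least 2-fold more enriched in the 148 kidney and 31 less, a split of 9 and 36 with TMM scaling and 13 and 36 per count outside 7SL RNA. With the minimum in every library the split of the remaining 10 genes was 8 and 1 on CPM and 5 and 2 per count outside 7SL RNA, and with no minimum 7880 and 6892 on CPM, which carries the shift of 0.95, but 7357 and 7844 per count outside 7SL RNA.

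The authors' peaks numbered 1430 in the 148 IP library and 1487 in the CK IP library, called once per library. Exons and UTRs held 194 CK peaks (13%, 11.4% to 14.9%) and 52 peaks of the 148 library (3.64%, 2.73% to 4.74%). In 3′ UTRs, where most microRNA sites lie, there were 61 CK peaks and 11 in the 148 library. The 148 list had no peak on chromosomes 2, 3 and 13, where the CK list had 48, 115 and 330. These contrasts therefore depend in part on the chromosomes where each list called peaks. The CK list held 3′ UTR peaks in Podxl, a podocyte surface protein (chr4:58826461-58833390, 26 reads, 3 in the control), where the 148 list has a smaller peak (chr4:58830031-58831220, 3 and 0), Gclm, a glutathione synthesis enzyme (chr2:225843751-225851780, 16 and 3), and Hnf4a, a transcription factor of the proximal tubule (chr3:159962551-159965450, 12 and 3), all chosen after their values were seen. The 148 list held a 3′ UTR peak in Calcr (chr4:28627831-28630210) with 5 reads and 0 in the control, at an adjusted p of 0.00380 in the authors' list, and the CK list had no Calcr peak. In the 148 list, chromosome 4 peaks of 3 reads, such as those in Gcc1 and Dysf, had that same adjusted p. The control was at 0 in 96.2% of the 148 peaks, so neither value set Calcr apart. The count tables list Calcr at 0 in all 4 libraries, over 2 transcript models. The median peak in either list rested on 3 reads.

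Most of the highest-scoring peaks lay outside exons. In the 148 library they were a pair of intergenic peaks beside Zmat2 (chr18:29648126-29648330 with 303 reads and chr18:29647716-29647920 with 286), a peak at Rn5s (chr12:1510426-1510650, 278 reads), one upstream of Ccdc107 (chr5:58994601-58995200, 565 reads) and one upstream of Gtf3c6 (chr20:45357071-45357275, 144 reads). In the CK library they were an intronic peak in Tex14 (chr10:74742601-74743000, 793 reads), an intergenic peak near LOC102547101 (chr1:221156641-221158800, 3706 reads), the Ccdc107 peak (729 reads), and exonic peaks in Ssfa2 (chr3:66602126-66603575, 8 reads) and in Slc12a1, the salt transporter of the thick ascending limb (chr3:117422451-117423900, 13 reads). The control had 0 reads at the Ssfa2 and Slc12a1 peaks. Their rank follows from scores whose scale differed by chromosome. In the CK list a chromosome 3 peak in Ehd4, on 5 reads, scored 202, and the chromosome 4 peak in Podxl, on 26 reads, 29.2. Scores are thus not comparable across chromosomes. In human, the genes of structural RNAs lie in these places, with vault RNAs beside ZMAT2 and RMRP beside CCDC107.

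The peak sets shared little. Of the 148 peaks, 40 (2.80%) overlapped a CK peak by at least 1 bp, where 1000 random shifts gave a median of 19 (95% of shifts 11 to 28, highest 34). Among the peaks of at least 50 reads, 9 in the 148 and 14 in the CK list, 6 were shared. Chromosome 4 held 1315 of the 148 peaks (92.0%) and 940 CK peaks (63.2%), beside 4.20% and 4.49% of the counts outside 7SL RNA, and chromosome 13 held another 330 CK peaks. Peak numbers on other chromosomes are therefore not comparable with those on chromosome 4.

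**Figure D3:**
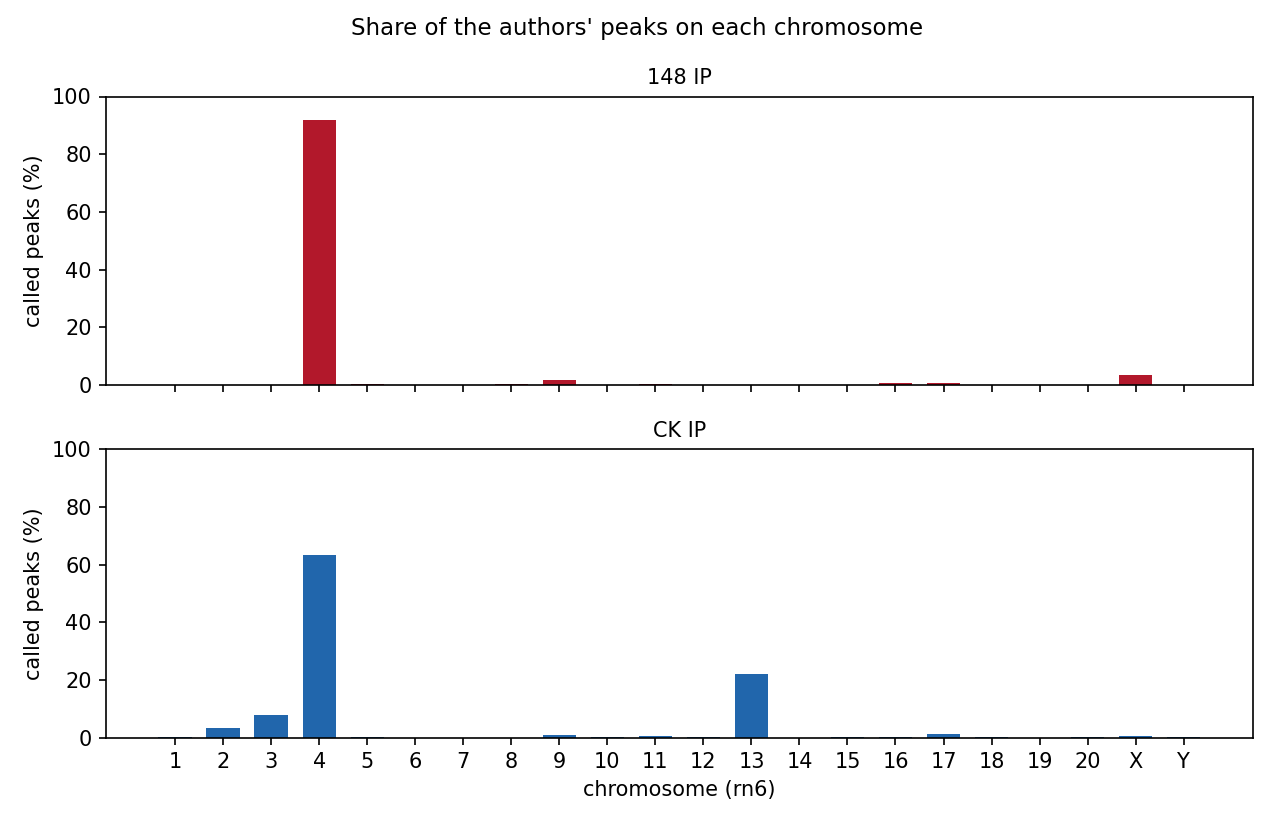
Percent of the authors' peaks on each rn6 chromosome (bars) in the 148 IP library (upper panel) and the CK IP library (lower panel). Chromosome 4 held 92.0% of the 148 peaks and 63.2% of the CK peaks.

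The authors' deposited table lists 694 regions that differ between the IP libraries, 421 higher in the 148 IP and 273 higher in the CK IP. Among the 50% of regions with the largest absolute Z scores, a choice made after seeing the data, the authors' deposited table has 116 and 231. That cut lies at 2.40, the Z score that the authors' deposited table gives to 7 against 1 higher in the 148 IP. To 7 against 1 higher in the CK IP the authors' deposited table gives -2.53. Equal signals were thus cut unequally, and no conclusion is drawn from the turn towards CK. In the authors' deposited table, exons or UTRs held 48 of the CK-higher regions (17.6%, 13.3% to 22.6%) and 18 of the 148-higher regions (4.28%, 2.55% to 6.67%). Most of those CK-higher regions lay on chromosomes 1, 2, 3 and 13, where the 148 list had no peak. Fth1, Fyb, Dido1 and Glul are examples. On chromosome 4, where both lists had many peaks, the authors' deposited table has exonic regions in both directions. The contrast in exonic shares thus depends in part on where each list called peaks. Ranked by the ratio of the signals, the largest CK-higher regions in the authors' deposited table were near LOC102547101 (59 against 1, and 1606 against 31), in an exon of Fth1 (58 against 1), in an exon of Slc12a1 (31 against 1) and near Igfbp5, a growth factor binding protein (20 against 1). Fyb and Dido1 followed there at 15 against 1, and LOC102547116 and Cers6 at 13 against 1, as the authors' deposited table gives them. By the same ratio, the authors' deposited table had, higher in the 148 IP, Psmd10 at 17 against 1, with LOC102548534, Cct6a-ps1, LOC686129 and RGD1559446 at 15 against 1. LOC102549020, Trim24, Lrrtm4, Dlgap1 and Da2-19 had 13 against 1 in the authors' deposited table. None of the 10 largest 148-higher regions by ratio lay in an exon or UTR. Exonic regions of LOC103692483 had larger signals but smaller ratios in the authors' deposited table, at 58 against 15 and 59 against 17.

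Calcr stood in the middle of the differences: the authors' deposited table gives its 3′ UTR (chr4:28628921-28629121) a signal of 7 in the 148 IP and 1 in the CK IP, with a Z score of 2.40. The same Z score is the median size over the authors' deposited table, which starts at 2.06. Signals were 10 or less in both libraries in 633 regions of the authors' deposited table (91.2%), and 509 regions (73.3%) lay on chromosome 4. Of the microRNA machinery list only Drosha appeared in the authors' deposited table, higher in the CK IP, and of the proximal tubule list only Slc13a3, also higher there. Their regions lay on chromosomes 2 and 3, where the 148 list had no peak.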

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

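The tests in this part, and the minimum of 10 reads per kidney, were chosen after the results were seen. Among the 54 genes other than 7SL RNA past the count minimum, 10 genes and 1 gene list moved in opposite directions between IP and input in the 148 and the CK kidney, by at least 2-fold on each side per count outside 7SL RNA and with at least 10 reads per kidney. Each value is the log2 enrichment in the 148 kidney minus that in the CK kidney, and the difference itself was not tested, since each group holds 1 library. Eef1a1, the translation elongation factor, stood at -9.83. Pck1, the gluconeogenic enzyme of the proximal tubule, stood at -5.61. Pnisr, Srrm2 and Rsrp1, all linked to RNA splicing, stood at -5.06, -4.26 and -3.85, the last as a bound because its 148 IP count was 0. Myo18a, an unconventional myosin, stood at -4.63. Wdfy3, an autophagy scaffold, stood at -4.56, and Smg1, a kinase of nonsense-mediated decay, at -4.15. LOC688018 stood at -3.68. The calcium and phosphate handling list, on 8 and 19 counts in the 148 kidney and 96 and 17 in the CK kidney, stood at -3.12, but rested on Slc34a1: without it the ratios were 0.382 (0.121 to 1.04) and 1.5 (0.821 to 2.88). LOC102553290 alone went the other way, at 2.62. Of the 11, 8 had both counting intervals off 1.

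LOC102553290, at 18 counts, was lowest in the CK IP library. The other flagged genes passed the count minimum through the CK IP library alone, and the flag required opposite directions. Their high CK IP counts and their lower 148 IP than input, such as Eef1a1 at 1 and 32 counts, therefore follow from the selection. Without that filter, the proximal tubule list, fixed beforehand, had 658 counts in the CK IP library. It had 48, 71 and 53 in the 148 IP, 148 input and CK input libraries. On the 148 side, abundant housekeeping genes, a list added after seeing the data, were 3.46-fold lower in the IP than in the input (2.28 to 5.39). That list holds the flagged gene Eef1a1, and without it the list was 2.42-fold lower (1.54 to 3.88). The only explanation examined for that side was background in the 148 IP library, given below. For the high CK IP library, depth alone is argued against, because proximal tubule counts of the CK IP library thinned to the 148 IP depth kept a median of 479.5 (457 to 500), beside 48 counted there. An exchange of the CK IP and input libraries is argued against as well, because Atp6v1b1 was 153-fold higher in the CK input than in the CK IP (51.8 to 746) and Rn5s 3.31-fold higher in the IP, the directions seen in the 148 kidney. Background such as genomic DNA as the only source of housekeeping gene reads is argued against in the inputs, because these genes had 9.11 (6.87 to 12.1) and 11.6 (8.20 to 16.3) times the reads per kilobase of muscle and neuron genes in the 148 and CK inputs, and 22.1 and 23.7 times those of olfactory receptors, though reads of processed pseudogenes were not set apart. In the 148 IP library it stays open for these genes, at 2.59 (1.60 to 4.05) and 6.67 times; it is no account of 7SL RNA or Rmrp there, with 152657 and 1059 counts. A share of such background in place of kidney messenger RNA stays open in the other libraries: proximal tubule markers had 1.26, 1.86 and 2.02 times the reads per kilobase of muscle and neuron genes in the 148 IP, 148 input and CK input libraries, but 3.24, 4.51 and 4.15 times those of olfactory receptors, and 44.1 times those of muscle and neuron genes in the CK IP library. An effect of the 148 condition on Ago2 binding, or an IP that worked in only 1 kidney, was not tested and cannot be separated with 1 library per group.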

How the results depend on the processing

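The alternatives scaled to counts outside 7SL RNA, alone or with another count minimum, genes with a single transcript model and the split by Z score were chosen after seeing the data. No paired test was made: the groups of each comparison share at most 1 replicate number, and no test across genes of IP against input over both kidneys together was made. Pseudocounts of 0.1 and 5, genes with a single transcript model and 1 peak per gene left all counts of genes and peaks within 1.5 times. TMM scaling gave 3 genes higher and 3 lower for 148 IP over input, 9 higher for 148 IP over CK IP and 9 for the difference of enrichments; it moved the proximal tubule median log2 ratio to -4.06 for 148 IP over CK IP and -3.57 for the difference, and reversed Rmrp to -0.19, -0.11 and -0.12 for 148 IP over input, 148 IP over CK IP and the difference. Scaling to counts outside 7SL RNA gave 4 higher and 3 lower for 148 IP over input, proximal tubule medians of -3.96 and -3.37, and Rmrp at -0.10 for 148 IP over input. Both scalings remove the shift made by the 7SL share. With no count minimum, genes with a few reads entered: 5791 higher and 5143 lower for 148 IP over input, 5480 and 5097 for CK IP over input, 6378 and 4918 for 148 IP over CK IP, 5529 and 4891 for the inputs, and 7880 and 6892 for the difference. Proximal tubule medians were then 2.08, -1.56 and -0.53 for CK IP over input, 148 IP over CK IP and the difference, at percentiles of 99.69, 0.035 and 25.96 among matched random lists, against 41.65, 7.95 and 87.13 with the minimum and 89.21, 21.31 and 39.54 among unmatched lists. Requiring the minimum in every library left fewer genes: 8 higher and 0 lower for 148 IP over input, 2 and 3 for CK IP over input, 9 and 0 for 148 IP over CK IP, and 8 and 1 for the difference. Per count outside 7SL RNA the splits were near even with no minimum: 5040 higher and 5951 lower for 148 IP over input, 5403 and 5228 for CK IP over input, 5300 and 5555 for 148 IP over CK IP, 5517 and 5245 for the inputs, and 7357 and 7844 for the difference; with the minimum in every library they were 1 and 1, 2 and 4, 5 and 2, 0 and 0, and 5 and 2, in the same order. Protein-coding genes alone gave 5 higher for 148 IP over input, 2 lower for CK IP over input, 6 higher for 148 IP over CK IP and 8 for the difference. Shared peaks fell from 40 to 16 with 50% reciprocal overlap and to 13 in the stricter lists. The stricter differential table kept 116 regions higher in 148 of 421 and 231 higher in CK of 273. That turn towards CK cannot be read as a result, because the Z score differs by direction for equal signals. Where no reason is given, the cause was not tested. Of single gene and list values, 175 stayed within counting error (percentiles within 5), 35 moved further and 4 reversed from a 2-fold call, the last all Rmrp. Values under 2-fold also changed sign: Ago2 for 148 IP over input, from 0.76 to -0.45 with TMM and -0.39 outside 7SL RNA, and for 148 IP over CK IP, from 0.15 to -0.95 and -0.87; Rmrp for CK IP over input, to -0.07 and -0.20, and for the inputs, to -0.08 outside 7SL RNA; and Slc3a1, with 0 counts in the 148 input, for the difference, from -0.08 to 2.80 with a pseudocount of 0.1 and 2.31 outside 7SL RNA. Seed matches, and overlap without regard to strand, were not run, as no transcript sequence or strand was used here. Depth limits all of this, since 1 read is worth 5.47 CPM in the 148 IP library.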

Other observations

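In this part, the tests on Atp6v1b1 and on chromosome 4, the values without 1 member of a list and the single genes named were chosen after the results were seen. Cell types beside the tubule gave few reads. Red blood cell markers had 24 counts in the CK IP, 18 of them of Hbb (beta globin), against 0 in the 148 IP, 0 in the 148 input and 1 in the CK input library. Endothelial markers were 4.44-fold higher in the CK IP than in its input (1.74 to 14.5), with Kdr, a VEGF receptor, at 23 and 2 counts, and 2.67-fold (0.735 to 14.6) without it. Fibroblast and smooth muscle markers were 7.40-fold higher (2.34 to 37.6) with the collagen gene Col3a1 at 26 and 0, and 2.06-fold (0.529 to 11.6) without it; between the IP libraries they differed by 1.14-fold (0.660 to 2.02, lower in the 148 IP), and without Col3a1 were 2.46-fold higher in the 148 IP (1.08 to 5.97). Kidney injury genes were 8.33-fold higher (2.09 to 72.3), with Vim, vimentin, at 19 and 1, and 4.94-fold (0.662 to 219) without it. Aqp2, the water channel of collecting duct principal cells, had 26 counts in the CK IP and 0 in each of the other libraries. Immune cell markers had 17 and 7 counts in CK IP and input, 13 and 0 of them of lysozyme Lyz2. In the 148 kidney, inflammation genes were 4.54-fold lower in the IP than in the input (1.83 to 13.5), and had a ratio of 0.397 (0.110 to 1.21) without Nfkbia, at 1 and 14 counts.

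The other groups had the following ratios of IP over input. Published miR-24-3p targets had ratios of 1.43 (0.760 to 2.76) in the 148 kidney and 1.46 (0.696 to 3.27) in the CK kidney. Podocyte markers had 1.38 (0.545 to 3.65) and 1.38 (0.693 to 2.88), but 10.5 (1.53 to 452) in the 148 kidney without Magi2, on 11 and 1 counts, and immediate early genes 1.56 (0.852 to 2.92) and 1.40 (0.839 to 2.39). Stone and crystal proteins had 1.91 (0.407 to 11.8) and 1.26 (0.733 to 2.24), thick ascending limb markers 0.477 (0.0431 to 3.33) and 1.23 (0.573 to 2.82), and distal convoluted and connecting tubule markers 1.11 (0.320 to 4.01) and 0.540 (0.244 to 1.18), the last 0.103 (0.0112 to 0.462) without Trpm6, on 2 and 12 counts. Cell cycle genes had 0.607 (0.199 to 1.71) and 0.529 (0.147 to 1.84), and adrenal, liver and fat markers 1.59 (0.524 to 5.32) and 0.617 (0.0826 to 4.61). Zinc finger genes were 1.33-fold lower in the 148 IP (1.09 to 1.61) and had a ratio of 0.969 in the CK kidney (0.800 to 1.18). Histone genes were 2.47-fold lower in the CK IP (1.38 to 4.51; ratio 0.561, 0.290 to 1.08, without H1fx) and had a ratio of 0.875 in the 148 kidney (0.467 to 1.63). Without Rmrp the list of structural small RNAs held almost only microRNA genes and had ratios of 0.542 (0.318 to 0.905) and 0.552 (0.337 to 0.901). Abundant housekeeping genes, added after seeing the data, were 3.46-fold lower in the 148 IP (2.28 to 5.39) and 5.60-fold higher in the CK IP (4.42 to 7.20). Without Eef1a1 they were 2.42-fold lower in the 148 IP (1.54 to 3.88) and 3.42-fold higher in the CK IP (2.64 to 4.49). Urothelium markers had 2, 8, 1 and 0 counts in the 148 IP, 148 input, CK IP and CK input libraries, nuclear-retained long RNAs 1, 6, 8 and 1, and sex genes 2, 0, 7 and 2. Between the IP libraries, kidney injury genes were 2.47-fold lower in the 148 IP (1.09 to 6.28) and inflammation genes 2.68-fold (1.05 to 8.08), with ratios of 1.03 (0.293 to 3.37) without Vim and 0.855 (0.220 to 2.96) without Nfkbia. Immune cell markers were 12.4-fold lower there (1.95 to 519) on 1 and 17 counts, and adrenal, liver and fat markers 4.56-fold higher (1.17 to 25.8) on 10 and 3, with ratios of 0.342 (0.00694 to 3.46) without Lyz2 and 2.74 (0.584 to 16.9) without Cfd. The tables listed 0 of the mitochondrially encoded genes.

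Atp6v1b1 was high in both inputs, at 171 and 283 counts, and low in both IP libraries, at 3 and 3. More collecting duct RNA in the inputs is argued against, because the other collecting duct markers, on 24 and 62 counts, stood at 0.510 in inputs over IP libraries (0.304 to 0.829), and at 0.878 (0.501 to 1.51) on 24 and 36 counts without Aqp2, which had 26 counts in the CK IP library alone. The design gives no group that bears on this difference between fractions beyond IP and input, and no biological explanation was tested.

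Most called peaks lay on chromosome 4 in both lists. More RNA from that chromosome is argued against, because it held 4.20% of the counts outside 7SL RNA in the 148 IP library (3.98% to 4.43%) and 4.49% in the CK IP library (4.29% to 4.70%). A lower read threshold in the peak calls there is a candidate explanation: called peaks went down to 2 reads on chromosome 4 in both lists and to 3 on chromosome 13 in the CK list, but not under 4 reads elsewhere in the 148 list and not under 4 elsewhere in the CK list.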
